A study of Mus musculus with 16 samples.

How the data were processed

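RNA of whole skin of 7-week-old mice was measured in 16 libraries, made with a strand-specific kit from RNA extracted with a column kit, per the labels' protocols. The labels give topical treatment for 4 days, while the titles run to day 5, and when each treatment began is not given in the sources used here. Titles place the libraries in 8 groups of 2, SDS at days 0, 1, 3 and 5 with or without Topsym. That Topsym is a fluocinonide preparation is background knowledge, not stated in the labels.

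The deposited table holds a normalised expression signal for each of 32078 genes, made from read counts. Per the submitters' processing notes, reads were trimmed with Trim Galore 0.6.7, aligned to mm10 with HISAT2 2.2.1, counted with featureCounts 2.0.3 and normalised with DESeq2 2.11.40.8. Whether the counting used the strand is not given in the sources used here, so reads of genes that overlap on opposite strands may be mixed. In every library, 100% of the deposited values were whole multiples of a step, within 1e-04, so whole read counts could be recovered. The scaling equals median-of-ratios size factors of those counts. Even numbers made up 69.9 to 76.8% of counts from 1 to 20, as if the mates of a fragment were often counted apart. Libraries held 15199656 to 32066246 recovered reads, and the 10 highest genes took 4.91 to 14.8% of them. Positions came from GENCODE M21 for 31983 genes, and 24 symbols occurred more than once.

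Genes with a value of at least 10 in at least 2 libraries were kept, 19189 in all. Differences of log2(value + 1) were fitted for the 8 groups together with limma 3.58.1 in R 4.3.3, with a trend of variance on level, which left 8 residual degrees of freedom, and moderated p-values were adjusted over all genes in each comparison by Benjamini and Hochberg. The threshold was an adjusted p of 0.05. The 15 comparisons were each later day against day 0 in each arm, day 5 against day 1 of SDS alone, Topsym against none at each day and averaged over days 1, 3 and 5, and the difference between the arms in the change from day 0 (the interaction). The comparisons, lists and rule for named genes were fixed before the data were examined.

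For SDS alone against day 0 and for Topsym averaged over days, the named genes were the 10 largest rises and the 10 largest falls past the threshold, with a mean of at least 100 in the higher group, no overlap between the libraries compared and no predicted models. Other comparisons used the first 5 each way, each list its 4 largest members at most, and 16 genes were followed everywhere. A single gene among those picked by this rule is not reported here. Where a group had 0 reads, a floor on the fold was taken from 3 reads over the group, as if each read were a separate count. Where it had 1 to 3 reads, the ratio of means is given with a 95% counting interval. Differences of changes and averages over days take no such floor. Reads of Sprr2, Krt6, Saa, Lce3, Defb, Mup and hemoglobin genes can be shared between near copies.

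Of 35 lists of cell type, tissue and pathway genes, 34 had at least 4 measured members and were tested with camera of limma, at a correlation between genes of 0.01, with p-values adjusted over the lists of a comparison. The muscle, immediate early and clock lists were set to track tissue below the skin, handling and time of collection. The sex-linked list had 1 of 6 genes measured, Xist, and was not tested. Xist stood at 8687 ± 394, 6942 ± 893, 4271 ± 166 and 3131 ± 22.7 at days 0, 1, 3 and 5 of SDS alone and at 8081 ± 443, 7051 ± 67.3, 7512 ± 14.6 and 3156 ± 10.5 with Topsym.

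The fit was tested on simulated data, drawn from negative binomial distributions with the means and dispersions of the real libraries, with day 1 of SDS set equal to day 0 except for chosen genes, over 18824 genes. It recovered 40 of 67 genes changed 1.5-fold (59.7%), 49 of 67 changed 2-fold (73.1%) and 58 of 66 changed 4-fold (87.9%), with 5 false calls (3.29% of calls). For lists, in Topsym against none at day 1, a list moved by simulation passed the test, and 4 of 200 random lists fell under a p of 0.05. Each gene was drawn independently, so the simulation could not test the correlation between genes set for the lists. Within groups, the chi-square per degree of freedom of the recovered reads was 3.13 to 6.98, or 1.56 to 3.49 when halved for mates counted apart.

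Alternatives were a pseudocount of 4, no filter, TMM factors of edgeR 4.0.16 on top of the deposited scaling, only the libraries compared, a robust variance prior, the replicate number as a block, a log2 change of at least 1 as well, each library left out in turn, and count tests with edgeR and DESeq2 1.42.0 on recovered reads. At day 1 of SDS alone the count tests called 5860 and 5712 genes, and at day 1 of Topsym against none 2524 and 2642. For lists, an estimated correlation, fry and the block were tried. TMM moved the median change by at most 0.043 in size. Like the deposited scaling, TMM takes most genes as unchanged, so it cannot test that scaling where most genes were called. At day 5 against day 0, 66.5% of genes were called without Topsym and 70.2% with it, so small changes there depend on the scaling. Another baseline for the arm with Topsym, and averages without a day, were chosen after seeing the data.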

Results

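Whole skin of mice was profiled by RNA sequencing over a course of topical sodium dodecyl sulfate (SDS, a detergent that irritates skin), with and without Topsym, a trade name of preparations of fluocinonide, a strong glucocorticoid for the skin. The 16 libraries form 8 groups of 2, at days 0, 1, 3 and 5 in each arm. They held 15199656 to 32066246 reads each, and 19189 of 32078 genes passed the filter on low values. When SDS or Topsym was applied relative to each day is not given in the sources used here. What the day 0 group with Topsym had received is therefore unknown, and every result that uses it as a baseline rests on those 2 libraries. No title names a group without SDS at days 1, 3 or 5. Changes from day 0 therefore mix SDS with time, animals and tissue sampled, which cannot be told apart.

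Values are normalised reads, as mean ± SD of 2 libraries. Changes are differences of log2(normalised reads + 1) with their standard error (SE) and the adjusted p of limma. Nothing in the labels says that the libraries of a group came from separate animals, so the p-values measure only the spread between these libraries, which may be technical. Intervals and floors cover counting error only, and take each read as a separate count. Where the mates of a fragment were counted apart, the intervals are too narrow and the floors too high. The genes that lead each comparison were those with both libraries of one group above both of the other. Counts of list members are over all genes tested, and the count adjusted over the list alone is the same unless it is given. Shifts of muscle, immediate early or clock genes may come from tissue below the skin, handling or the hour of collection. Whether these differed between groups was not tested. Positions are on mouse genome GRCm38.

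At day 1 of SDS alone, the skin carried more RNA of glucocorticoid target genes and of stress keratins and antimicrobial genes, and less of muscle, collagen, cell division and fat synthesis. The comparison with day 0 asks which genes differ first in the course of the detergent. Pdk4, which encodes a kinase that holds pyruvate back from oxidation (ENSMUSG00000019577, chromosome 6, 5483351 to 5496309), rose from 638 ± 70.5 to 17195 ± 164 (log2 4.75, SE 0.11, adjusted p = 1.06e-14). The cornified envelope gene Sprr1b rose from 308 ± 12.6 to 6104 ± 452. The muscle ubiquitin ligase gene Trim63 rose from 741 ± 14.6 to 9494 ± 416. Serpina3m, Slpi, Lce3d, Angptl4, Saa3 and Cyp2b23 were also among the largest rises, at log2 3.68 to 4.30.

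The largest fall at day 1 was that of Myh7, a slow muscle myosin (chromosome 14, 54970684 to 54994626), from 141 ± 14.4 to 1.74 ± 1.09 (log2 -5.74, SE 0.96, adjusted p = 0.000251). Lrrc38, Crabp1, Acaa1b, Ky, Stra6, Xlr3b, Aox4 and Myod1 fell by log2 values between -5.46 and -3.06. Tmem254c, the remaining gene of the 10, passed at -3.12, but the call was lost without SDS_D0 replicate 2 (-2.29) or without SDS_D1 replicate 2 (-1.56), with only the libraries compared in the fit, with a robust variance prior, and with DESeq2 on recovered reads (-2.67). In all, 5037 genes passed the threshold, 2449 higher and 2588 lower, of which 512 and 578 changed at least 2-fold.

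Of 23 glucocorticoid target genes, 21 were higher and 1 lower at day 1 (median log2 1.03, list adjusted p = 1.02e-25). Among them Fkbp5 rose from 2226 ± 28.3 to 10873 ± 57.7 (log2 2.29, SE 0.04, adjusted p = 1.58e-15). Stress keratins and antimicrobial genes of the epidermis were higher for 17 of 22 and lower for 2 (median log2 2.04, list adjusted p = 1.22e-17). Epidermal differentiation genes went both ways, 16 higher and 8 lower of 26, with Krt2 at log2 -2.16 and Cnfn at 1.67. Basal keratinocyte genes were higher for 10 of 12 and lower for 1, at a median of only 0.33. Neutrophil genes were higher for 6 of 16 (median log2 0.70, list adjusted p = 6.32e-05), led by Clec4d at 4.27. Of 20 monocyte and macrophage genes 12 were higher and 1 lower, and 13 were higher adjusted over the list alone. The red blood cell list had a larger median than both, at 0.97, and mitochondrially encoded genes had a median of -0.52.

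Fatty acid synthesis genes fell as a group at day 1, with 16 of 19 lower and 0 higher (median log2 -0.40, list adjusted p = 1.69e-11; adjusted over the list alone 16 lower and 1 higher). Thrsp, at -2.94, and Elovl6, at -2.32, led them. Fatty acid oxidation genes were higher for 11 of 25 and lower for 3, and the list lost its call with an estimated correlation (adjusted p = 0.00107, and adjusted p = 0.1 with an estimated correlation; 12 higher adjusted over the list alone). Skeletal muscle genes were lower for 17 of 18 (median log2 -0.53, list adjusted p = 1.92e-15), beside Myh7, Ky and Myod1. Cell proliferation genes were lower for 19 of 30 and higher for 1 (median log2 -0.48, list adjusted p = 6.12e-08; 20 lower adjusted over the list alone). Collagen and fibroblast genes were lower for 16 of 22 and higher for 1, led by Lum at -2.37. Hair cycle signal genes were lower for 16 of 30 and higher for 0, and 18 were lower adjusted over the list alone. Of the 34 lists, 12 were higher, 9 lower and 13 without a call, and 4 of the calls were lost with an estimated correlation. The adipocyte list, without a call, had a median of -0.02 while its test pointed up.

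At day 3 of SDS alone, the skin held a burst of neutrophil and acute phase RNA, and lost RNA of T cells, dendritic cells, hair follicle stem cells and collagen. This comparison with day 0 asks how far inflammation has built up. Saa3, a serum amyloid of injured skin (ENSMUSG00000040026, chromosome 7, 46711998 to 46715700), rose from 20.9 ± 15.8 to 39741 ± 1642 (log2 11.04, SE 0.30, adjusted p = 2.87e-14). Ngp, a granule protein of neutrophils (chromosome 9, 110419747 to 110423012), had 0 reads at day 0 and 2931 ± 26.9 at day 3, at least 2328-fold higher. The stefin gene Stfa2l1 had 0 reads at day 0 and was at least 1861-fold higher, and Cxcl5, a chemokine for neutrophils, at least 1436-fold. Cxcl3 rose to 5458 ± 1.28 from 2 reads in all (ratio 6196, 95% counting interval 1800 to 53700). Ppbp, from 2 reads, and Fpr1, from 1 read, had ratios of 2587 (684 to 20400) and 2730 (516 to 114000). Retnlg, Mmp8 and Clec4d completed the 10 largest rises, at log2 11.22, 10.93 and 10.45.

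Myh7 had 0 reads at day 3 and was at least 104.5-fold lower than at day 0. Myod1, Lrrc38 and Aqp4 fell at the same time, by log2 -5.85, -5.47 and -5.43. Cpz, a carboxypeptidase, fell from 1378 ± 172 to 26.0 ± 0.967 (log2 -5.67, SE 0.74, adjusted p = 6.65e-06). Thrsp, a regulator of fat synthesis (chromosome 7, 97412938 to 97417730), fell from 1304 ± 19.1 (log2 -4.96, SE 0.70, adjusted p = 1.58e-05). Tmem233, Serpina3b and Cyp4f37 fell by -5.36, -5.14 and -5.13. Mup17 fell by -5.07, from day 0 libraries that differed widely (775 ± 744) and from a gene with near copies in the genome. In all, 9518 genes passed, 4869 higher and 4649 lower, with 1880 and 1934 changed at least 2-fold.

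All 16 neutrophil genes measured were higher at day 3 (median log2 7.90, list adjusted p = 1.77e-14). Chemokines were higher for 15 of 25 and lower for 3 (median log2 1.65; 16 higher adjusted over the list alone), and acute phase genes for 11 of 14, with 1 lower. Cytokines were higher for 12 of 17 and lower for 1, led by Csf3 at 7.72. Monocyte and macrophage genes were higher for 18 of 20 and endothelial genes for 14 of 17, with Selp at log2 4.64. Adjusted over the list alone 1 macrophage gene was lower and 15 endothelial genes were higher. T cell and NK cell genes were lower for 13 of 17 (median log2 -1.65, list adjusted p = 0.000341), with Cd8a at 0 reads, at least 10.36-fold lower. Dendritic and Langerhans cell genes were lower for 11 of 14 (median log2 -2.01), with Cd207 at -3.89, and 1 was higher adjusted over the list alone.

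Stress keratins and antimicrobial genes were higher for 20 of 22 at day 3 (median log2 4.14, list adjusted p = 1.06e-16), and Krt6a alone rose from 2562 ± 206 to 28904 ± 1357. Hair follicle stem cell genes were lower for 13 of 15 and higher for 1 (median log2 -1.43, list adjusted p = 4.72e-07). Hair cycle signals were lower for 22 of 30, with Wnt10b at -3.31. Collagen and fibroblast genes were lower for 18 of 22 and higher for 3, among them Col1a1 at -3.42 and Lox at 2.54. Repair proteases and matrix were higher for 17 of 22 and lower for 2, led by Tnc at 7.04 and Spp1 at 7.02. Fatty acid oxidation genes were higher for 14 of 25 and lower for 2, with Pdk4 at 6.04, and adipocyte markers for 11 of 20, with 3 lower. Sebaceous gland genes were lower for 11 of 16 and higher for 4, led by Cyp2g1 at -4.57. Glucocorticoid targets stayed higher, 22 of 23 (23 adjusted over the list alone). Red blood cell genes were higher for 7 of 7 (median log2 1.88), a measured fact that may reflect blood left in the tissue. Of 34 lists, 14 were higher and 10 lower, and 3 calls were lost with an estimated correlation.

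At day 5 of SDS alone, stress keratin, differentiation, cell proliferation and cholesterol synthesis genes were higher, while adipocyte, collagen, endothelial, muscle and hair follicle stem cell genes were lower. The comparison with day 0 asks what state the skin reaches at the end of the course. Sprr2b, a cornified envelope gene with close paralogs (ENSMUSG00000050092, chromosome 3, 92316620 to 92318085), went from 0 reads to 14398 ± 319, at least 11440-fold higher. Sprr2k, also at 0 reads at day 0, was at least 1261-fold higher. S100a9 rose from 107 ± 1.81 to 215730 ± 7350 (log2 10.96, SE 0.11, adjusted p = 4.26e-20), and S100a8 (chromosome 3, 90668978 to 90670035) from 32.4 ± 10.9 to 49039 ± 586. Krt6b (chromosome 15, 101676023 to 101680287) rose from 173 ± 31.2 to 146400 ± 1385 (log2 9.73, SE 0.11, adjusted p = 1.17e-19), with the caution that reads can be shared with Krt6a. Uox, urate oxidase, and the beta-defensin gene Defb3 each had 2 reads at day 0, with ratios of 3716 (95% counting interval 1080 to 32200) and 2652 (701 to 20900). Sprr2d, Lce3b and Serpinb3a rose by log2 9.84, 9.81 and 9.60.

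Among the falls at day 5, Mup17, Aqp4, Myod1 and Plaat1 had 0 reads, at least 363.7-fold, 149.7-fold, 97.68-fold and 71.54-fold lower than at day 0. Lep, the gene of the fat hormone leptin, fell from 312 ± 30.4 to 2 reads in all (ratio 0.00454, 95% counting interval 0.000551 to 0.0165). Tmem233 also fell to 2 reads (ratio 0.00316, interval 0.000381 to 0.0114). Thrsp fell from 1304 ± 19.1 to 6.40 ± 9.05 (log2 -8.46, SE 0.70, adjusted p = 1.61e-08). Cpz, Mylk4 and Ky fell by -8.53, -7.72 and -7.49. The day 5 libraries stood apart from those of other days: here 20636 and 20774 genes were detected, against at least 22875 in any library of another day, and the 10 highest genes took 10.3 and 10.8% of reads, against at most 7.06%. In all, 12759 genes passed, 5897 higher and 6862 lower, with 2302 and 4487 changed at least 2-fold.

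All 22 stress keratin and antimicrobial genes were higher at day 5 (median log2 7.42, list adjusted p = 5.93e-19), and 24 of 26 differentiation genes, with 1 lower. Cell proliferation genes were higher for 29 of 30 (median log2 1.43, list adjusted p = 3.82e-12), and Mki67 rose from 2688 ± 174 to 5300 ± 246. All 20 cholesterol synthesis genes were higher (median log2 1.30), led by Hsd17b7 at 3.28. Neutrophil genes were still higher for 14 of 16 with 1 lower (median log2 4.79). The interferon response was lower for 18 of 21 (median log2 -1.66). All 22 collagen and fibroblast genes were lower (median log2 -3.38, list adjusted p = 1.01e-15), with Col1a1 at -6.31. Adipocyte markers were lower for 17 of 20 and higher for 1 (median log2 -2.74, list adjusted p = 2.12e-08). Hair follicle stem cell genes were lower for 14 of 15, and Lgr5 (chromosome 10, 115450311 to 115587780) fell from 240 ± 40.4 to 7.11 ± 10.1 (log2 -5.94, SE 0.95, adjusted p = 3.97e-05). Endothelial genes were lower for 16 of 17, dendritic cell genes for 13 of 14 and muscle genes for 18 of 18 (median log2 -2.63).

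Of the 34 lists at day 5, 10 were higher and 16 lower, and 8 of these calls were lost with an estimated correlation. Macrophage genes were lower for 14 of 20 and higher for 3 (adjusted p = 0.00796, and adjusted p = 0.0767 with an estimated correlation). T cell and NK cell genes were lower for 15 of 17 and higher for 2 (adjusted p = 0.00602, and adjusted p = 0.0684 with an estimated correlation). Lipolysis genes were lower for 10 of 18 and higher for 3 (adjusted p = 0.0316, and adjusted p = 0.138 with an estimated correlation). Pigment cell genes were lower for 6 of 8 (median log2 -1.98, or -1.61 with Tyr, at 0 reads, set to its bound, adjusted p = 0.0454, and adjusted p = 0.148 with an estimated correlation). Hair cycle signals were lower for 27 of 30 and higher for 1 (median log2 -2.62, or -2.18 with members at 0 reads set to their bound). Acute phase genes went both ways, 6 higher and 6 lower of 14 (7 lower adjusted over the list alone), with a median of -0.92 beside a test that pointed up. Red blood cell genes were higher for 7 of 7 and immediate early genes lower for 13 of 17, with 4 higher.

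Day 5 against day 1 of SDS asks what separates the late from the early response. Between these days the epidermal genes Serpinb3a and Sprr2b rose by log2 10.30 and 12.52, while Pdk4 and most glucocorticoid targets fell. Sprr2a1 and Sprr2a2, each at 1 read at day 1, had ratios of 8368 (95% counting interval 1400 to 308000) and 4093 (684 to 151000), and Uox, at 2 reads, a ratio of 3370 (1010 to 30000). Pdk4 fell by -4.69 and Angptl4 by -5.15, and 18 of 23 glucocorticoid targets were lower with 2 higher (median log2 -1.19, list adjusted p = 3.07e-07). Mup17 and Pon1 had 0 reads at day 5, at least 434.1-fold and 54.1-fold lower, and Lep fell to 2 reads (ratio 0.00135, interval 0.000164 to 0.00489). Cpz and Cnn1 fell by -8.18 and -7.14. All 30 proliferation genes were higher (median log2 1.84), and adipocyte markers were lower for 19 of 20 with 1 higher. Mast cell genes were lower for 9 of 10 and higher for 1 (median log2 -1.86, list adjusted p = 0.00117). Between these days 12532 genes passed, 5789 higher and 6743 lower. The hair shaft list, without a call, had a median of 0 while its test pointed up.

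Among the 16 genes followed in every comparison, Pnpla2, the main fat lipase gene, went from 3484 ± 188 at day 0 to 9243 ± 601, 22734 ± 54.4 and 3382 ± 387 at days 1, 3 and 5 of SDS alone, and from 2237 ± 131 to 12893 ± 141, 11218 ± 96.3 and 2883 ± 7.27 with Topsym. Lipe, the other fat lipase gene, went from 904 ± 32.5 to 1795 ± 47.9, 3125 ± 32.5 and 844 ± 63.6 without Topsym, and from 676 ± 94.5 to 1979 ± 109, 2731 ± 17.4 and 1216 ± 60.8 with it. The fatty acid carrier gene Cd36 went from 1536 ± 215 to 3174 ± 22.2, 9110 ± 56.6 and 481 ± 47.5, and with Topsym from 702 ± 56.2 to 4592 ± 44.1, 7144 ± 45.0 and 336 ± 30.6. Adipoq held 1591 ± 167 at day 0 and 121 ± 14.4 at day 5 of SDS alone (log2 -3.71, SE 0.15, adjusted p = 1.19e-12), and 563 ± 55.1 and 102 ± 29.9 with Topsym. Ppargc1a fell from 159 ± 3.48 to 40.5 ± 2.90 at day 5 of SDS alone (log2 -1.95, SE 0.24, adjusted p = 2.33e-06).

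Il1b peaked at day 3 of SDS alone, at 4184 ± 133 from 106 ± 18.5 (log2 5.31, SE 0.14, adjusted p = 1.7e-14), and Ccl2 at 845 ± 111 from 170 ± 0.645, before it fell to 19.9 ± 16.1 at day 5. With Topsym, Ccl2 was highest at day 0, at 577 ± 59.0, and stood at 146 ± 24.4, 172 ± 7.51 and 14.5 ± 2.37 at days 1, 3 and 5. Tsc22d3, a glucocorticoid target (chromosome X, 140539528 to 140600659), stood at 6496 ± 410, 13166 ± 197, 9254 ± 190 and 4472 ± 133 over the days of SDS alone, and at 6518 ± 390, 11979 ± 75.0, 5377 ± 111 and 3127 ± 122 with Topsym. Krt6a reached 99473 ± 6517 and 96601 ± 5768 at day 5 without and with Topsym. Lef1 was low throughout, at 49.4 ± 16.3 at day 0 and 2.13 ± 0.998 at day 5 of SDS alone, where 3 reads remained (ratio 0.0431, 95% counting interval 0.00867 to 0.128). Shh did not pass the filter on low values.

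**Figure D1:**
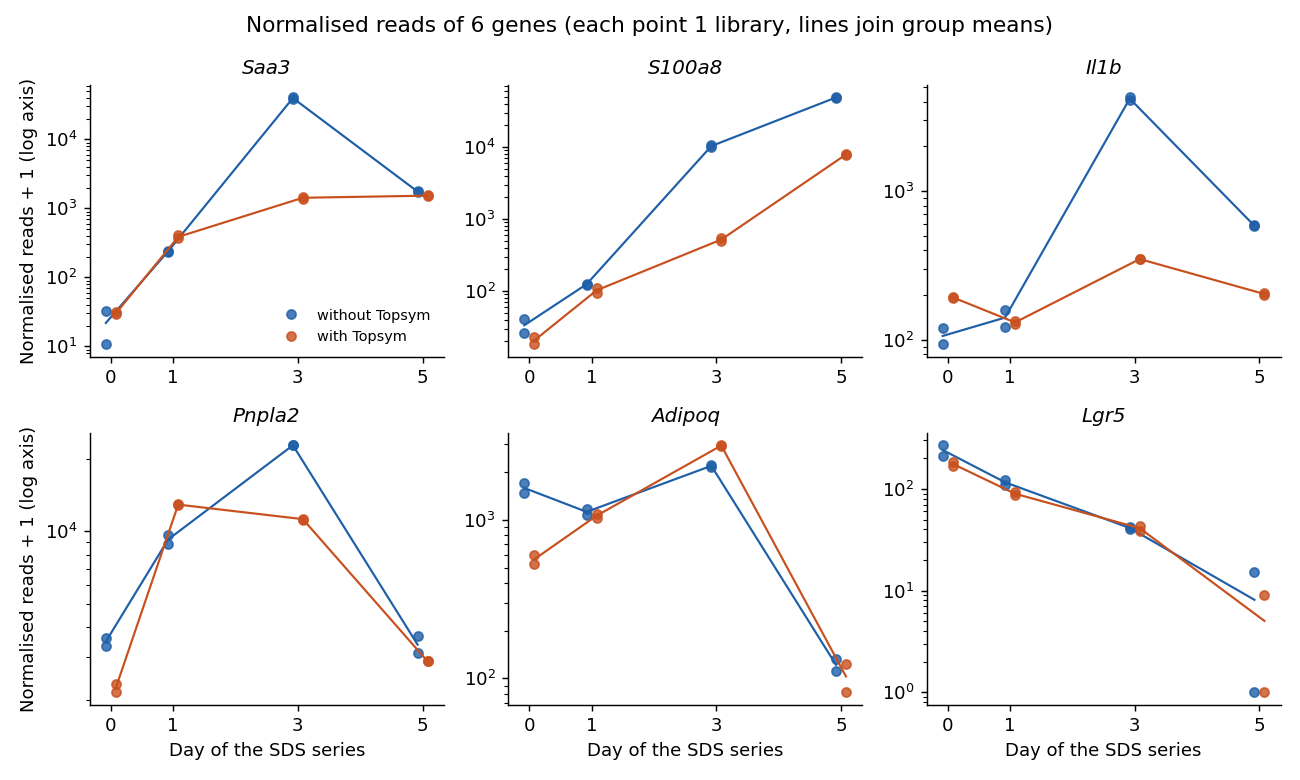
Normalised reads + 1 (log axis) of Saa3, S100a8, Il1b, Pnpla2, Adipoq and Lgr5 against day, without Topsym in blue and with Topsym in orange; points are libraries and lines join group means. Saa3 at day 3 stood at 39741 without Topsym and at 1425 with it.

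With Topsym, day 1 of SDS against its own day 0 brought more muscle, fat and sebaceous gland RNA and less hair shaft, interferon and red blood cell RNA. This comparison asks how skin under the glucocorticoid responds to the detergent. Ankrd1, a stress gene of muscle (ENSMUSG00000024803, chromosome 19, 36111961 to 36120099), rose from 3.44 ± 2.03 to 863 ± 4.52 (log2 7.68, SE 0.23, adjusted p = 1.04e-13). Pdk4 rose from 297 ± 58.5 to 25125 ± 30.7 (log2 6.41, SE 0.11, adjusted p = 1.45e-16), and Cyp2b23 from 4.06 ± 5.75 to 551 ± 15.7. Capn11 rose from 2 reads (ratio 128.0, 95% counting interval 39.2 to 1180), and Mrgprg, a sensory neuron receptor gene, by log2 6.66. Keratins of the hair follicle's inner root sheath fell furthest. Krt71 and Krt73 had 0 reads at day 1, at least 4736-fold and 486.7-fold lower, Krt72 was at least 163.8-fold lower, Krt27 fell by -7.76, and Krt25 fell to 2 reads (ratio 0.000214, interval 2.52e-05 to 0.000752). These calls rest on the day 0 libraries with Topsym: against day 0 without Topsym, a baseline chosen after the data were seen, Mrgprg stood at 0.08, the call of Krt71 was lost (-1.77, at 0 reads at day 1), and Krt27 stood on the other side, at 0.36, while Krt25, Krt72 and Krt73 had 0 reads in that group and at most 2 at day 1. With DESeq2 on recovered reads the calls of Krt73 (-11.95) and Krt72 (-10.38) were lost. The lists rest on that baseline as well: against day 0 without Topsym, the medians of the day 1 libraries with Topsym were 0.38 and 0.55 for interferon, -0.37 and -0.56 for sebaceous gland and 0.24 and 0.51 for red blood cell genes, all on the other side, 0.11 and 0.12 for muscle, 0.45 and 0.39 for adipocyte, 0.26 and 0.31 for fatty acid oxidation, and 0 and -0.02 for hair shaft genes.

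At this day 7830 genes passed, 3901 higher and 3929 lower, and of 34 lists 16 were higher and 9 lower. All 18 muscle genes were higher (median log2 1.45, list adjusted p = 4.4e-22), where they had been lower without Topsym. Adipocyte markers were higher for 17 of 20 (median log2 1.29) and sebaceous gland genes for 13 of 16, with 1 lower. Fatty acid oxidation genes were higher for 20 of 25 and lower for 1 (median log2 0.72, list adjusted p = 2.5e-10; 21 higher adjusted over the list alone). Glucocorticoid targets were higher for 18 of 23 and lower for 3, and Fkbp5 rose from 1754 ± 43.0 to 12135 ± 41.4 (log2 2.79, SE 0.04, adjusted p = 3.55e-17). Interferon genes were lower for 20 of 21 (median log2 -1.54), hair shaft genes for 22 of 24 (median log2 -5.81, or -5.69 with the Krt genes at 0 reads set to their bound), and red blood cell genes for 5 of 7 (7 adjusted over the list alone).

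At day 3 with Topsym, Krt6b rose from 90.2 ± 13.8 to 47911 ± 4331 (log2 9.04, SE 0.11, adjusted p = 6.13e-19), and Sprr1b from 322 ± 35.5 to 50447 ± 1186. Prl2c3, of the prolactin family, and the defensin gene Defb4 had 0 reads at day 0 and were at least 419.3-fold and 161.4-fold higher. Ankrd1 rose by log2 8.08. Krt25, Krt73 and Krt28 had 0 reads at day 3, at least 3466-fold, 525.0-fold and 381.7-fold lower, Krt71 had 3 reads (ratio 0.000204, 95% counting interval 4.02e-05 to 0.000569), and Krt27 fell by -9.01. Against day 0 without Topsym, the calls of Krt27 (-0.89) and Krt71 (-0.70) were lost, while Krt25 and Krt73 had 0 reads in both groups, and with DESeq2 the call of Krt73 was lost (-12.06). All 21 interferon genes were lower (median log2 -3.10), T cell and NK cell genes for 16 of 17, and macrophage genes for 15 of 20 with 4 higher (16 lower adjusted over the list alone), though against day 0 without Topsym the medians of these libraries were 0.07 and 0.03 for macrophage genes and -1.22 and -0.99 for interferon genes. Proliferation genes were higher for 29 of 30 (30 adjusted over the list alone) and cholesterol synthesis genes for 20 of 20. Of 10587 genes that passed, 5184 were higher and 5403 lower.

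At day 5 with Topsym, Krt6b reached 153950 ± 8422 (log2 10.73, SE 0.11, adjusted p = 2.3e-20). Lce3e, Lce3d and Sprr2b, which have close paralogs, rose by log2 9.20, 8.81 and 9.01, and Spink7 went from 0 reads to at least 400.3-fold higher. Krt73, Krt28 and the interferon gene Ifi206 had 0 reads, at least 217.0-fold, 157.8-fold and 179.2-fold lower, while Krt71 and Krt25 kept 2 reads each (ratios 0.000283 and 0.000526, intervals 3.8e-05 to 0.00114 and 5.65e-05 to 0.00169). Against day 0 without Topsym, which had 0 reads of Krt73 and Krt25, the call of Krt71 was lost (-0.73), and with DESeq2 the calls of Krt73 (-10.78) and Krt25 (-10.90) were lost. Interferon genes were lower for 21 of 21 (median log2 -5.21, list adjusted p = 1.9e-10), with medians of -2.70 and -2.63 for these libraries against day 0 without Topsym, dendritic cell genes for 13 of 14, and collagen genes for 22 of 22 (median log2 -4.61). Respiratory chain genes were higher for 27 of 28 (median log2 0.86, list adjusted p = 4.03e-10). Cytokines had a median of 0.00 on the lower side while their test, without a call, pointed up. In these libraries 19885 and 20411 genes were detected, and the 10 highest took 14.8 and 14.4% of reads. Of 13477 genes that passed, 6286 were higher and 7191 lower.

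The responses of the arms were set side by side, with no library in both. At day 1, 1727 genes were higher in both arms, where 497.9 would be shared if the calls were unrelated, and 1550 were lower in both (529.9 if unrelated). At day 3 these counts were 2776 (1315.4) and 2655 (1309), and at day 5 4666 (1931.8) and 5282 (2571.5). Correlations of the log2 changes across genes, which are not independent of each other, were 0.482, 0.52 and 0.751 (Pearson) and 0.46, 0.462 and 0.765 (Spearman) at days 1, 3 and 5. Genes called in opposite directions, each also past the threshold of the test of the difference, numbered 390, 1452 and 601.

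**Figure D2:**
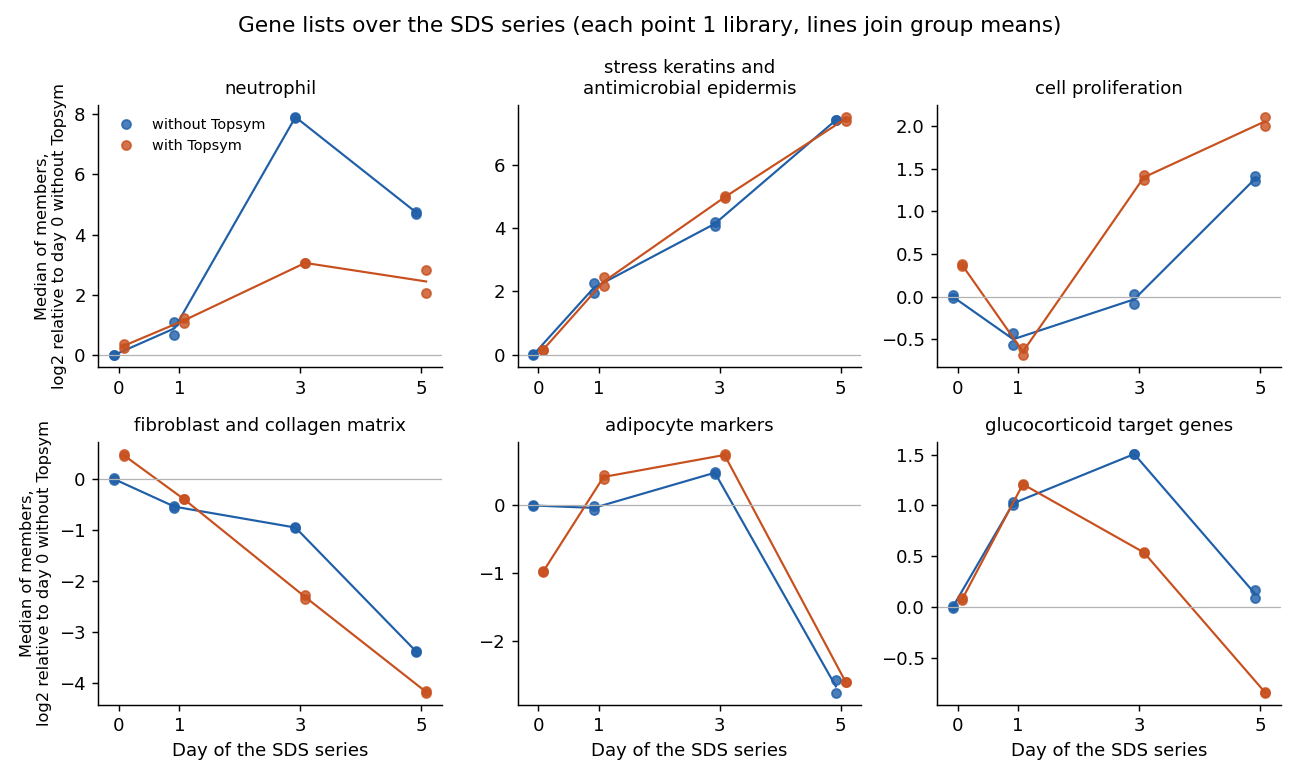
Median log2 change of the members of 6 gene lists against day, relative to day 0 without Topsym, with points for libraries and lines for group means (blue without Topsym, orange with it). All 16 neutrophil genes were higher at day 3 of SDS alone, at a median of 7.90.

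At day 0, the skin with Topsym already differed from the skin without it, with more hair shaft, interferon, hemoglobin and macrophage RNA, and less muscle, fat and sebaceous gland RNA. The comparison asks whether the arms started alike. Krt25, an inner root sheath keratin of growing hair (ENSMUSG00000035831, chromosome 11, 99315516 to 99322951), had 0 reads without Topsym and 3832 ± 140 with it, at least 3044-fold higher. Krt71 (chromosome 15, 101733949 to 101743109) rose from 2.48 ± 1.02 to 5647 ± 372 (log2 10.69, SE 0.76, adjusted p = 2.1e-08) and Krt27 from 5.81 ± 1.99 to 1848 ± 22.0. Krt73 and Tchhl1 were at 0 reads without Topsym, at least 461.1-fold and 294.4-fold higher, though the call of Krt73 was lost with DESeq2 on recovered reads (log2 11.87). Lower with Topsym were Mrgprg (-6.57), Mup17 (-5.26), Pon1 (-4.45) and Panx3 (-2.84). Myh7 was lower too (-4.13), a call lost without SDS_D0_Topsym replicate 2 (-3.67).

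Hair shaft genes, a list that also holds inner root sheath keratins, were higher for 18 of 24 at day 0 with Topsym (median log2 4.55, list adjusted p = 1.71e-16; 19 adjusted over the list alone). Interferon genes were higher for 20 of 21 (median log2 2.45, list adjusted p = 8.51e-21; 21 adjusted over the list alone), led by Oasl1 at 3.84. Red blood cell genes were higher for 6 of 7 (7 adjusted over the list alone), macrophage genes for 18 of 20 with 2 lower, and Fos rose by log2 2.74. Muscle genes were lower for 18 of 18 (median log2 -1.52, list adjusted p = 2.54e-38), and sebaceous gland genes for 14 of 16 (median log2 -1.56; 15 adjusted over the list alone). Adipocyte markers were lower for 16 of 20, fatty acid synthesis genes for 14 of 19 with 1 higher (15 lower adjusted over the list alone), and cholesterol synthesis genes for 15 of 20 (18 adjusted over the list alone). Glucocorticoid targets went both ways, 9 higher and 4 lower of 23 (10 and 5 adjusted over the list alone; adjusted p = 0.0316, and adjusted p = 0.0598 with an estimated correlation), and Fkbp5 was lower, at log2 -0.34. In all, 4230 genes passed, 2073 higher and 2157 lower, with 460 and 474 changed at least 2-fold.

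**Figure D3:**
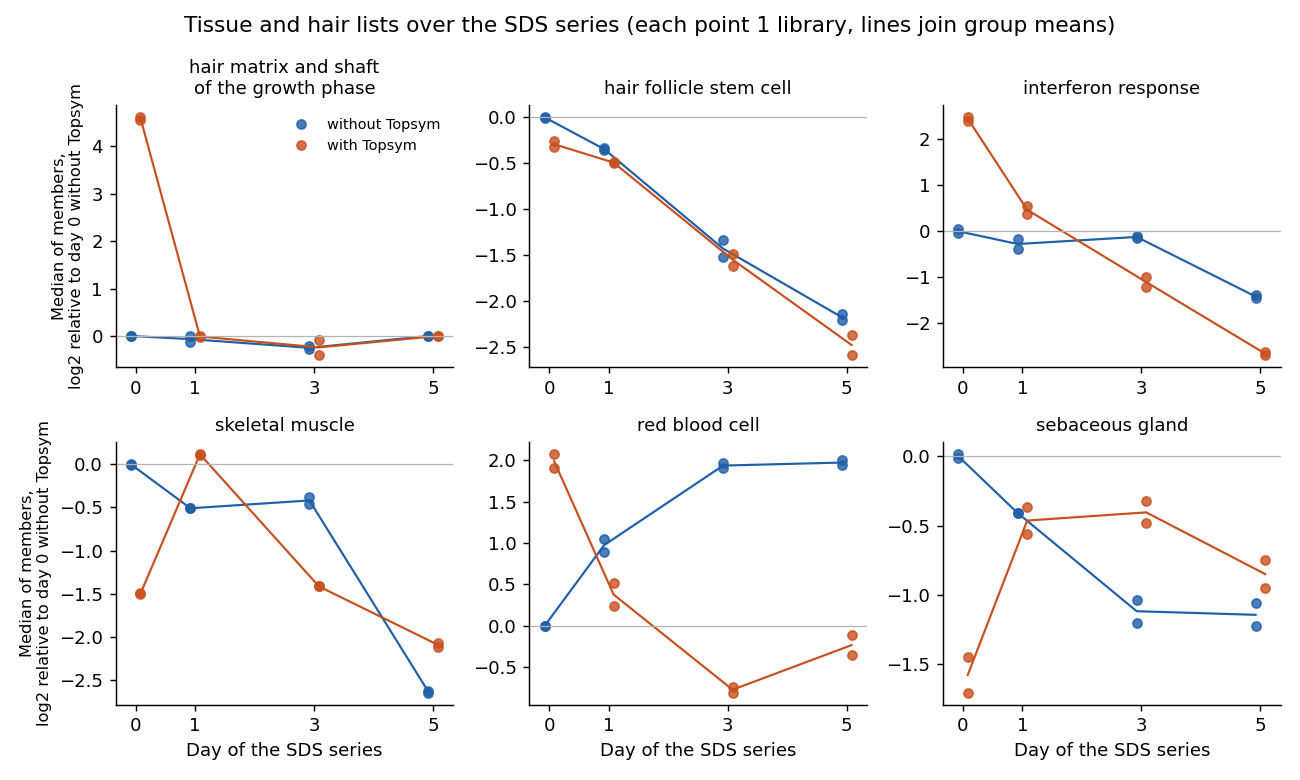
Median log2 change of 6 lists of hair, tissue and interferon genes against day, relative to day 0 without Topsym; points are libraries and lines group means, blue without Topsym and orange with it. The hair shaft list stood at a median of 4.55 at day 0 with Topsym.

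At day 1, where the arms were most alike, muscle and macrophage genes were higher and dendritic cell genes lower with Topsym. The comparison asks whether the glucocorticoid changes the early response. Chil3, a macrophage chitinase-like gene (chromosome 3, 106147554 to 106167564), stood at 443 ± 2.65 with Topsym and 18.0 ± 0.697 without (log2 4.55, SE 0.23, adjusted p = 3.34e-09). Capn11, a calpain gene (chromosome 17, 45630204 to 45659325), had 0 reads without Topsym and was at least 95.23-fold higher. Klk13 and C7 were higher by log2 2.59 and 2.39, and Srp54b by 3.30, a call lost with a robust variance prior and without SDS_D1 replicate 1 (3.09) or SDS_D1_Topsym replicate 1 (2.58). Sprr2i (-2.38), Pglyrp2 (-2.17), Zfp69 (-2.08) and Nrg1 (-1.67) were lower, and Ccl17 (-1.79), lost without SDS_D1_Topsym replicate 2 (-1.73). Only 1881 genes passed, 1058 higher and 823 lower, with 143 and 75 changed at least 2-fold. The count fell to 921 or 924 without SDS_D1_Topsym replicate 1 or 2, to 999 without SDS_D1 replicate 1 and to 1260 without SDS_D1 replicate 2.

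Muscle genes were higher with Topsym for 16 of 18 at day 1 (median log2 0.64, list adjusted p = 1.92e-34), macrophage genes for 14 of 20 with 1 lower (17 and 2 adjusted over the list alone), and interferon genes for 9 of 21 (14 higher and 2 lower adjusted over the list alone). Dendritic cell genes were lower for 6 of 14 (median log2 -0.69, list adjusted p = 1.5e-09), with Ccr7 at -2.18, and basal keratinocyte genes for 7 of 12 (8 adjusted over the list alone). Of 23 glucocorticoid targets 7 were higher and 0 lower (9 higher and 2 lower adjusted over the list alone), at a median of 0.12. No hair shaft gene passed. Of 34 lists 13 were higher and 9 lower, and 9 of these calls were lost with an estimated correlation. The neutrophil and differentiation lists, without a call, had medians of -0.04 and -0.02 while their tests pointed up.

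At day 3, neutrophil, macrophage and chemokine genes were lower with Topsym, and cell proliferation and differentiation genes were higher. This is the comparison that asks whether the glucocorticoid dampens the peak of inflammation. Saa3 stood at 1425 ± 86.4 with Topsym and 39741 ± 1642 without (log2 -4.80, SE 0.30, adjusted p = 1.51e-09), S100a8 at 518 ± 30.7 and 10337 ± 439, and Il1b at 349 ± 0.334 and 4184 ± 133. Ngp was lower by -8.89, Retnlg by -8.06 and Ppbp by -7.66. Ly6g had 0 reads with Topsym, at least 123.1-fold lower (its call was lost with DESeq2 on recovered reads, log2 -9.96), and Itgb2l kept 2 reads (ratio 0.00405, 95% counting interval 0.000539 to 0.0163). Epgn, a growth factor of keratinocytes (chromosome 5, 91027464 to 91035215), stood at 6679 ± 21.3 with Topsym and 764 ± 51.6 without (log2 3.13, SE 0.10, adjusted p = 3.72e-13). The division genes Depdc1a, Pclaf and Cip2a were higher by 3.26, 2.88 and 2.73, and Prl2c3 by 2.80. Krt6a was higher, at 78274 ± 2355 against 28904 ± 1357.

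Neutrophil genes were lower with Topsym for 15 of 16 at day 3 (median log2 -4.35, list adjusted p = 1.67e-12), macrophage genes for 20 of 20, chemokines for 20 of 25 with 3 higher, and acute phase genes for 12 of 14 with 1 higher. Cytokines were lower for 9 of 17 and higher for 3, led by Csf3 at -4.95 and Osm at -4.71. Glucocorticoid targets themselves were lower for 20 of 23 and higher for 1 (median log2 -0.97, list adjusted p = 5.54e-12), with Fkbp5 at -0.60 and Mt2 at -1.72. Proliferation genes were higher for 30 of 30 (median log2 1.65, list adjusted p = 3.83e-22), differentiation genes for 25 of 26 with 1 lower, basal keratinocyte genes for 10 of 12 and cholesterol synthesis genes for 18 of 20. Collagen genes were lower for 19 of 22, endothelial genes for 15 of 17, muscle genes for 18 of 18 (median log2 -1.04) and red blood cell genes for 6 of 7 (median log2 -2.63). Mitochondrially encoded genes were higher for 9 of 13 (11 adjusted over the list alone; adjusted p = 9.61e-05, and adjusted p = 0.222 with an estimated correlation). The immediate early and hair shaft lists had no call, the latter with a median of 0 and a test that pointed up. In all, 8401 genes passed, 4000 higher and 4401 lower, with 850 and 1734 changed at least 2-fold.

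At day 5, neutrophil and macrophage genes were again lower with Topsym, and muscle and immediate early genes were higher. The muscle and immediate early lists were set to track tissue below the skin and handling. The comparison asks whether the arms still differ at the end of the course. Uox stood at 71.8 ± 27.3 with Topsym and 3273 ± 21.1 without (log2 -5.54, SE 0.65, adjusted p = 3.47e-06), and S100a8 at 7899 ± 213 and 49039 ± 586. Alox8, a skin lipoxygenase gene, was lower by -5.29 and Cxcl3 by -4.25. Ankrd1 stood at 1228 ± 84.7 with Topsym and 41.2 ± 5.91 without (log2 4.87, SE 0.23, adjusted p = 7.54e-11). Lars2 (4.29), Arc (3.86) and the muscle gene Mybph (3.84) were higher. Thrsp (5.58), Rgs1 (-4.86) and Cd177 (-4.19) passed as well, calls that were lost when only these 4 libraries were fitted. The day 5 libraries, with 19885 to 20774 genes detected, stood apart from those of other days in both arms. In all, 8976 genes passed, 4339 higher and 4637 lower, with 937 and 1816 changed at least 2-fold. The count was 4028 with only those libraries in the fit.

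Neutrophil genes were lower with Topsym for 14 of 16 at day 5 (median log2 -2.10, list adjusted p = 1.34e-07) and macrophage genes for 19 of 20. Red blood cell genes were lower for 6 of 7 (median log2 -1.89), collagen genes for 17 of 22 with 1 higher, and endothelial genes for 12 of 17 with 3 higher. Repair proteases and matrix were lower for 16 of 22 and higher for 1, led by Mmp13 at -3.79. Clock genes were lower for 10 of 15 (median log2 -1.22, list adjusted p = 3.73e-07; 11 adjusted over the list alone), with Hlf at -2.45 and Dbp at -1.65. Immediate early and heat shock genes were higher for 14 of 17 (median log2 0.49, list adjusted p = 8.62e-08), with Fosb at 2.93 and Atf3 at 1.87. Muscle genes were higher for 15 of 18 and lower for 2 (16 higher adjusted over the list alone), and proliferation genes for 22 of 30. Glucocorticoid targets were lower for 15 of 23 and higher for 4 (5 higher adjusted over the list alone), with Klf9 at -1.73. The mast cell and hair shaft lists had no call, with medians of -0.06 and 0 beside tests that pointed up.

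Whether the change over the SDS course differed between the arms was tested as the difference of the changes from each arm's own day 0. Each of these results therefore rests on all 4 libraries of day 0. At day 1 the responses differed for 3307 genes, 1761 with a higher and 1546 with a lower change under Topsym, at day 3 for 7481 (3739 and 3742) and at day 5 for 6701 (3311 and 3390). The muscle list had the clearest difference at day 1, with 18 of 18 genes higher (median log2 2.01, list adjusted p = 1.05e-46). Topsym against none stood at muscle medians of -1.52 at day 0 and 0.64 at day 1, so the day 0 difference was the larger. Sebaceous gland genes were higher for 11 of 16 (13 higher and 1 lower adjusted over the list alone) and fatty acid synthesis genes for 15 of 19. Red blood cell genes were lower for 7 of 7, and hair shaft genes for 18 of 24 (21 adjusted over the list alone). Ankrd1 rose by log2 4.97 more with Topsym (SE 0.32, adjusted p = 9.33e-09), and Myh7 and Mrgprg by 8.43 and 7.57. Capn11 was higher too, with 2 reads or fewer in 3 of the groups.

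At day 3, the macrophage list had the clearest difference, with 20 of 20 genes lower in their change under Topsym (median log2 -2.54, list adjusted p = 2.04e-20). Interferon genes were lower for 20 of 21 (21 adjusted over the list alone; median log2 -3.51), neutrophil genes for 15 of 16 (16 adjusted over the list alone), collagen genes for 19 of 22, and red blood cell genes for 7 of 7. Topsym against none stood at interferon medians of 2.45 at day 0 and -1.11 at day 3, so the day 0 difference was the larger. Il1b differed by -4.45 (SE 0.20, adjusted p = 3.49e-11), and Saa3 by -5.48. Ppbp and Ngp were lower as well, with 2 reads or fewer at day 0 without Topsym. Differentiation genes were higher for 23 of 26 with 1 lower, and Mup17, Pon1, Acvr1c and B3galt2 by 7.98, 4.28, 4.15 and 3.96. Myh7, at 0 reads at day 3 without Topsym, was higher too. At day 5, interferon genes were lower for 21 of 21 (median log2 -3.20, or -2.91 with Ifi44, at 0 reads, set to its bound), macrophage genes for 20 of 20 and red blood cell genes for 7 of 7, while muscle genes were higher for 18 of 18 (median log2 2.16, list adjusted p = 1.03e-27). Relative to day 0 without Topsym, the day 5 libraries stood at interferon medians of -1.449 and -1.396 without Topsym and -2.701 and -2.633 with it. Their muscle medians were -2.628 and -2.65 without Topsym and -2.068 and -2.121 with it. Topsym against none at day 0 stood at 2.45 for interferon and -1.52 for muscle, so the day 0 difference was again the larger. Ankrd1 differed by 7.70 (SE 0.32, adjusted p = 1.73e-11), and Thrsp by 6.35, and Myod1 and Plaat1, at 0 reads at day 5 without Topsym, were higher. The hair cycle list at day 3, and the stress keratin and stem cell lists at day 5, had no call and a median and test of opposite sign.

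Averaged over days 1, 3 and 5, neutrophil, chemokine, acute phase and dendritic cell genes were lower with Topsym, and cell proliferation and differentiation genes were higher. The average leaves out the day 0 libraries and does not show a change at each day. Cxcl3 was lower by -3.35. Ppbp, a platelet and neutrophil chemokine gene, and Npy1r, both at 0 reads at day 5 with Topsym, and Cxcl9 and Mmp25, at 2 reads there, were lower too. Alox8, Acod1, Cxcl2, Il18rap and Mefv were lower by log2 values between -2.77 and -2.57. Epgn was higher by 1.96 (SE 0.06, adjusted p = 1.66e-13), Arc by 1.97, Plin1 by 1.65 and Fosb by 1.61. Thrsp (2.78), Spink7 (2.42) and Kbtbd8 (1.71) were higher as well, and so were Capn11, Myod1 and Ankef1, each at 0 reads at some day without Topsym. Il1b was lower by -1.73 and S100a8 by -2.41. Saa3, lower by -1.44, stood on the other side without day 3, at 0.24, a setting chosen after the data were seen.

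Over these days neutrophil genes were lower with Topsym for 15 of 16 (median log2 -2.23, list adjusted p = 1.39e-11), chemokines for 22 of 25 with 3 higher, acute phase genes for 12 of 14, and dendritic cell genes for 12 of 14. Proliferation genes were higher for 29 of 30 (median log2 0.70, list adjusted p = 4.13e-17), differentiation genes for 21 of 26 and cholesterol synthesis genes for 20 of 20. Glucocorticoid targets were lower for 18 of 23 and higher for 2 (median log2 -0.49), red blood cell genes for 7 of 7, and clock genes for 10 of 15 with 1 higher (2 higher adjusted over the list alone). Fatty acid uptake genes had no call, with 5 higher and 7 lower of 17. The basal keratinocyte and hair shaft lists, without a call, had medians of -0.01 and -0.05 beside tests that pointed up. In all, 8650 genes passed, 4245 higher and 4405 lower, with 285 and 931 changed at least 2-fold.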

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

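The first set of results stands out because a test of the difference between the arms' responses to SDS passed the threshold. That test was fixed before the values were looked at. The splits within days were planned with the comparisons. The test of the fasting genes was set after the pattern it addresses was seen. By then the changes of all genes had been fitted, but the medians of that list had not been computed. All other tests weighed below were chosen only after the result was seen.

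At day 1 the responses differed for 3307 genes and 23 lists, 2 of these list calls lost with an estimated correlation. The largest differences were higher with Topsym for Myh7 (8.435), Mrgprg (7.572), Capn11 (6.91), Ankrd1 (4.97) and Mup10 (10.437). The call of Mup10 was lost without any 1 of 6 libraries, at 5.72 without SDS_D0 replicate 2, 6.455 without SDS_D1_Topsym replicate 1 and 10.437 without either library of SDS_D1 or of SDS_D0_Topsym, and with no filter, a robust variance prior or only the libraries compared. They were lower for Krt25 (-11.983), Krt71 (-11.404), Krt73 (-9.183), Prr9 (-7.943) and Krt27 (-7.64), with the calls of Krt25 lost with DESeq2 (-14.841) and of Krt73 with edgeR (-12.245) and DESeq2 (-12.058). The differences of Krt25, Krt71 and Krt73, here and at the later days, rest mainly on their reads in the day 0 libraries with Topsym. Of the genes followed everywhere, Pnpla2 (1.121), Lipe (0.564), Adipoq (1.416), Cd36 (1.656) and Fkbp5 (0.502) differed upward, and Il1b (-0.968), Ccl2 (-2.241) and Mki67 (-0.444) downward. At day 1 itself Il1b stood at -0.095 for Topsym against none, without a call, so most of its difference comes from day 0. Lists called in opposite directions in the arms, with a difference that passed, were fatty acid synthesis (0.948), the respiratory chain (0.392), sebaceous gland (1.548), muscle (2.013) and red blood cells (-2.671). Their opposite directions rest on the day 0 libraries with Topsym: against day 0 without Topsym, the day 1 libraries with Topsym stood on the same side as SDS alone for fatty acid synthesis (-0.42 and -0.445), the respiratory chain (-0.05 and -0.044), sebaceous gland (-0.368 and -0.56) and red blood cells (0.243 and 0.514), and on the other side for muscle (0.114 and 0.12). Groups at 0 to 3 reads entered the values of Mup10, Capn11, Krt25, Krt71, Krt73 and Prr9, which depend on the 1 added to each value and are no bound.

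At day 3 the responses differed for 7481 genes and 28 lists, 6 of these list calls lost with an estimated correlation. Genes differed upward for Mup17 (7.982), Myh7 (5.443), Pon1 (4.282), Acvr1c (4.15) and B3galt2 (3.963), and downward for Krt25 (-11.904), Ppbp (-10.278), Krt83 (-10.141), Krt73 (-9.962) and Ngp (-9.69). The call of Krt25 was lost with edgeR (-14.968) and DESeq2 (-14.877), and that of Krt73 with DESeq2 (-14.702). Saa3 (-5.48), Pnpla2 (-0.38), S100a8 (-3.645), Il1b (-4.452), Ccl2 (-4.037), Fkbp5 (-0.255) and Tsc22d3 (-0.788) differed downward, and Adipoq (1.921), Cd36 (0.773), Krt6a (1.671) and Mki67 (1.597) upward. Within day 3 Adipoq was higher with Topsym by only 0.425 and Cd36 was lower, so these upward differences come mostly from day 0. Lists called in opposite directions were macrophages (-2.536), differentiation (1.469), fatty acid synthesis (0.945), sebaceous gland (2.139), red blood cells (-4.847) and mitochondrially encoded genes (1.161; adjusted p = 0.0934 with an estimated correlation, by camera of limma). Against day 0 without Topsym, the day 3 libraries with Topsym stood on the same side as SDS alone for macrophages (0.065 and 0.028), fatty acid synthesis (-0.316 and -0.358), sebaceous gland (-0.484 and -0.326) and mitochondrially encoded genes (-0.077 and -0.113), and on the other side for differentiation (0.895 and 0.905) and red blood cells (-0.733 and -0.805). The values of Myh7, Krt25, Ppbp, Krt73 and Ngp hold groups at 0 to 3 reads and are no bound either.

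At day 5 the responses differed for 6701 genes and 23 lists, 2 of these list calls lost with an estimated correlation. Genes differed upward for Ankrd1 (7.697), Thrsp (6.349), Myod1 (6.202), Mup17 (5.257) and Plaat1 (5.222), and downward for Krt25 (-12.365), Krt73 (-10.155), Krt71 (-9.659), Tchhl1 (-7.887) and Krtap7-1 (-7.758). Calls were lost with edgeR for Mup17 (5.529), Krt71 (-7.045) and Krtap7-1 (-10.819), and with DESeq2 for Krt25 (-15.69) and Krt73 (-13.982). The values of these 5 genes and of Myod1, Plaat1 and Tchhl1 hold groups at 0 to 3 reads and are no bound. Pnpla2 (0.413), Lipe (0.951), Adipoq (1.227), Cd36 (0.607) and Fkbp5 (0.573) differed upward, S100a8 (-1.962), Il1b (-2.395), Ccl2 (-1.945) and Tsc22d3 (-0.522) downward, and so did the red blood cell list (-3.718). Topsym against none at day 5 itself went the other way for Pnpla2 (-0.226), Cd36 (-0.516) and Adipoq (-0.269, without a call). Their upward differences therefore come from the gap between the arms at day 0. Ccl2 stood at -0.189 at day 5, without a call, so most of its difference comes from day 0 too. The call of Ccl2 was lost without SDS_D0_Topsym replicate 1 (-1.841) and with only the libraries compared. The test for a single library far from its group needs at least 4 libraries in a group, and was not applied to groups of 2.

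The libraries of a group held nearly equal levels of muscle, blood and fat genes that differed several fold between groups. If both came from a single tissue sample or pool, their shifts should be like those of random lists, and 3 of 24 shifts passed the 95% level of such lists, the most the prediction allowed, so the test is borderline. A first version of that test, replaced after its result of 9.84% was seen, compared the difference within pairs with the range between groups. A library deposited in duplicate is excluded by a halved chi-square of at least 1.5647. Separate animals dissected alike were not told apart from a pool, and that stays open.

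Hair shaft genes were high in both day 0 libraries with Topsym. Growing hair in this skin predicts a rise of the Krtap genes, and the median of the 55 with any read was 2.866. For the 16 with a read in another group it was 2.943, above the highest 2.5% of matched random lists (0.003). Most of those 16 had 0 reads at day 0 without Topsym, so their change could not be negative. Among those with reads there, Krtap3-2, by far the highest, did not rise (-0.039), while Krtap17-1 (0.978), Krtap3-3 (1.114) and Krtap1-3 (2.7) did. A first version on the 24 genes past the filter, seen before, gave 4.452. An effect of Topsym at every day is excluded, since the highest median at days 1, 3 and 5 was 0. Distances argue against labels exchanged with another day, since that group lay nearest to day 0 without Topsym, at a median difference of 0.2597 against 0.3808 for the next. They do not exclude an exchange, since days 0 and 1 without Topsym lay only 0.2924 apart. An effect of Topsym at day 0 itself remains confounded with the hair cycle of those animals, and stays open.

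Glucocorticoid targets were higher at day 1 in both arms. The arm without Topsym rose by a median of 1.029, so Topsym put on the sampled skin does not explain the rise there, if the titles hold. Whether the arms shared animals is not given in the sources used here, so Topsym reaching that skin from elsewhere stays open. More muscle is excluded in the arm without Topsym only, by a muscle median of -0.526. With Topsym the muscle list rose by a median of 1.448, so more muscle stays open there, as does a part of Topsym in the rise. Food deprivation or another catabolic state predicts a rise of 14 fasting and muscle catabolism genes. The lower of the arms' medians was 0.756, without Topsym, with 13 of 14 higher in each arm. With Topsym these genes rose by a median of 1.179, less than the muscle list, so more muscle could account for their rise there. Some of these genes are known glucocorticoid targets, so food deprivation cannot be told from another source of glucocorticoid, and the biological reading of a stress response to SDS stays open too.

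For Topsym against none over days 1, 3 and 5, 2 of 100 splits of the libraries within days, the real split among them, called at least as many genes as the real 8650. The other called 8695 and exchanges the arms at day 1 only, and splits that mixed the arms at any day called 7598 at most. Both libraries of a group could come from a single tissue sample, so splits that mix a day could part technical replicates, and chance in how animals fell into arms stays open.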

How the results depend on the processing

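Most results held under every alternative. Of 5913 alternative values of 412 gene results, 5684 kept direction and side of the threshold, 126 became weaker, 44 stronger and 59 reversed. Among 2228 values with a library left out, where the lone library of a group is assumed to vary like the other groups, 63 were weaker and 35 reversed. Of 510 list tests, 346 passed, 288 with an estimated correlation, 471 with fry, 350 with a replicate block and 347 with TMM. Few reads limit genes near 0, where counting error dominates. Unless said, the cause was not tested. Day 0 without Topsym as the baseline and averages without day 1, 3 or 5 were chosen after seeing the data.

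A log2 change of at least 1 as well lowers counts by construction. At days 1, 3 and 5 against day 0 it left 1090, 3814 and 6789 genes without Topsym and 2240, 4496 and 7919 with it, and 6539 for day 5 against day 1. For Topsym against none it left 934, 218, 2584 and 2753 genes at days 0, 1, 3 and 5 and 1216 over days, and for the interactions 907, 3189 and 2761. With only the libraries compared in the fit, Topsym against none at day 5 called 4028 genes against 8976. At day 3 the same setting raised the count, to 9127 from 8401. Median absolute log2 differences within groups were largest at day 5, at 0.1856 without and 0.1984 with Topsym, against at most 0.1482 elsewhere. The spread shared by all groups may thus be too small for day 5, which was not tested. Leaving out a library lowered the count at day 1 to between 921 and 1260.

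With the number 1 or 2 as a replicate block, counts were close to the unblocked ones, for example 4923 against 5037 at day 1 of SDS. Deviations of libraries with the same number correlated from -0.1903 to 0.2234 over 28 pairs of groups, 2 over 0.1 and 5 under -0.1. Between the arms at days 1, 3 and 5 they correlated at -0.0301, -0.0262 and 0.0017, so no pairing was seen there. At day 0 the arms correlated at 0.2234, the highest value, so pairing or a shared batch at day 0 is not ruled out.

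Against day 0 without Topsym as the baseline, values in the arm with Topsym reversed for Krt25 at day 1 (0.699) and day 5 (1.166), Krt27 (0.359), Adipoq (-0.578) and Il1b (0.312) at day 1, Ppargc1a at day 1 (-0.031) and day 3 (-0.454), Ccl2 at day 3 (0.023) and Pnpla2 at day 5 (-0.272). With edgeR, Pnpla2 at day 5 of SDS reversed (0.002), as did Lgr5 for Topsym at day 3 (0.024) and for the interaction at day 5 (-0.521, and -0.533 with DESeq2). With TMM, Lgr5 for Topsym at day 3 (0.034) and Saa3 for the interaction at day 1 (-0.015) reversed. Over days, without day 3, Saa3 (0.243), Pnpla2 (0.128), Adipoq (-0.174), Cd36 (0.008), Krt6a (-0.088), Lef1 (0.088) and Fkbp5 (0.194) reversed, and without day 5 Lipe (-0.027) and Cd36 (0.091).

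Leaving out a library changed the sign of genes near 0, at few reads, or with libraries of a group that differed widely. Saa3 and Ccl2 could stand far from 0 on either side, depending on the library left out. The extremes were -0.163 and 0.071 for Pnpla2 at day 5 of SDS. For Topsym at day 0 they were -0.135 and 1.493 for Saa3 and -0.059 and 0.07 for Tsc22d3, and at day 1 -0.288 and 0.097 for Il1b. At day 3 they were -0.097 and 0.08 for Lgr5 and -1.84 and 0.32 for Lef1. At day 5 they were -0.57 and 0.032 for Adipoq, -1.072 and 0.693 for Ccl2, -0.109 and 0.025 for Krt6a, and -2.338 and 1.59 for Lgr5. For the interaction at day 1 they were -0.811 and 0.818 for Saa3, -0.466 and 0.018 for Ppargc1a, -0.003 and 0.203 for Krt6a, and -0.1 and 0.243 for Lgr5. At day 3 they were -0.045 and 0.47 for Ppargc1a, and at day 5 -1.896 and 2.033 for Lgr5 and -0.535 and 0.136 for Lef1. Over days they were -0.075 and 0.126 for Adipoq, -0.906 and 0.404 for Lgr5, and -0.554 and 0.165 for Lef1.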

Other observations

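Lists of mast cell, fatty acid uptake, mitochondrial and clock genes were described only in part above. Mast cell genes were higher for 3 of 10 at day 1 of SDS alone (adjusted p = 0.0144 by camera of limma, and adjusted p = 0.0564 with an estimated correlation) and lower for 8 with 1 higher at day 5 (adjusted p = 0.0212, and adjusted p = 0.0684 with an estimated correlation). Fatty acid uptake genes were higher for 10 of 17 and lower for 3 at day 3 of SDS alone (median log2 0.90), and for 12 with 3 lower at day 3 with Topsym (median log2 1.23). Mitochondrially encoded genes were lower for 12 of 13 at day 3 of SDS alone (adjusted p = 8.63e-05, and adjusted p = 0.177 with an estimated correlation). Clock genes had no call over the days of SDS alone, with 7 of 15 higher and 6 lower at day 1, and 4 higher and 7 lower at day 5.

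The 14 fasting genes were chosen before their medians were computed, though the changes of all genes had been fitted by then. Trim63 and Txnip, which had been seen, were left out. Their median change was 1.179 at day 1 with Topsym, 1.664 and 0.966 at day 3 without and with it, and 0.328 and 0.155 at day 5, where it lay at percentiles 76.66 and 44.25 of random lists. Fbxo32, a ubiquitin ligase gene of wasting muscle, stood at 2458, 8078, 14281 and 3042 over the days of SDS alone, and at 1675, 8475, 4970 and 517 with Topsym. The lower of the arms' medians at day 1, 0.756 without Topsym, could come from a catabolic state of the animals or another source of glucocorticoid. This test cannot tell these apart. With Topsym the muscle list rose by 1.448 at day 1, so more muscle could also account for the rise there.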
